A study of Homo sapiens with 18 samples.

How the data were processed

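Trizol RNA of 18 Cal27 cultures was sequenced on an Illumina instrument, per the labels' protocols. The 6 groups of 3 libraries are high-glucose, glucose-deprived and 5 mM 2-DG medium, each with 10 nM CGRP or with control medium for 24 hours. The libraries are titled TG and capTG, which the design text reads as CGRP and control, while the growth protocol speaks only of different CM, so conditioned media or exchanged arms are not ruled out. The deposited table holds 1 raw count per gene and library for 60683 Ensembl gene IDs, per the file headers. The authors aligned the reads with HISAT2 before counting, per the submitters' processing notes, which name builds of both hg19 and GRCh38 without saying which gave the counts, so no coordinates are given. The program that counted reads, the annotation, the strand setting and the handling of genes that overlap are not given in the sources used here. For this reason values of close paralogs (AKR1C genes, metallothioneins, ribosomal proteins, HSPA1A and HSPA1B, SPRR genes) and of genes overlapped by others are uncertain. ASNS at 1.49 CPM and ALDOA at 6.36 CPM in the high-glucose control were low for genes of amino acid synthesis and glycolysis in a growing line.

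Totals ran from 28.04M to 32.66M counts per library, and all intervals cover counting error only. Symbols were found for 60370 of the IDs in a gene name table, and 42013 of these were symbols other than an Ensembl ID. Genes with enough counts (filterByExpr on the 6 groups, at least 10 counts, at least 15 in total) left 18159 to test. Counts were scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test with robust estimation, on all 18 libraries with 1 coefficient per group and 12 residual degrees of freedom. The common biological coefficient of variation was 9.44%. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05 and no fold threshold. Principal components used log2 CPM with a pseudocount of 2.

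The 9 comparisons were CGRP against control in each of the 3 media, the 3 contrasts between media without CGRP, the interactions of CGRP with deprivation and with 2-DG, and CGRP averaged over the media. Gene lists, 33 in all, were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 3 genes were tested, which left out markers of endothelial and of Schwann cells. Adjusted p of lists are over the 31 lists of a comparison. Camera with an estimated correlation and fry were also run, and fry tests whether the genes of a list move on balance one way, without comparing them with other genes. Median, mean and test differed in sign only for lists that did not shift. Of those described, these were Rap1 regulators with CGRP in each medium and with deprivation, mTOR pathway genes with CGRP in deprived medium, autophagy machinery with CGRP in 2-DG medium, and partial EMT genes with CGRP in 2-DG medium and with deprivation. Some lists share genes: cAMP/CREB-responsive genes and the AP-1 family share 5, and ATF3, SLC7A11, GDF15 and ME1 are each in more than 1 list. The groups, tests, lists, naming of genes and the alternatives not named below as later ones were set before the data were examined. Not every list that shifted is described. Named genes of a pairwise comparison are the 5 largest rises and 5 largest falls that passed, with an average log2 CPM of at least 1, an official symbol and no overlap of the 3 libraries of each group. To these come the 3 members with the smallest adjusted p of the shifted lists in order of p, and 16 genes fixed in advance, of which 1 is not reported here. Interactions and the averaged effect name the 5 largest differences each way. List members beyond these were chosen after their values were seen.

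Overlaps were counted as genes that passed in both comparisons, beside the number that independent changes would give, and correlations of log2 fold changes were taken across genes. For a gene with 1 to 3 counts in a group the ratio is given with its 95% counting interval. The test was checked on data simulated from the high-glucose libraries, with 200 of 18159 genes changed, 50 in each class. It recovered 84% of genes raised and 92% lowered 2-fold, and 74% and 62% of those changed 1.5-fold. It called 0.0557% of unchanged genes, 6.02% of its 166 calls. Camera called 2% of 100 unchanged lists before adjustment, which leaves co-regulated lists unchecked.

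The alternatives were DESeq2 size factors in edgeR (RLE), the DESeq2 1.42.0 Wald test, no low-count filter, a stricter filter (over 1 CPM in 3 libraries and a mean over 2 CPM), a fit of only the groups compared, a replicate block, and each library left out in turn. Chosen after seeing the data were leaving out both libraries that stand apart, scaling by total counts, an offset for a smooth trend with transcript length (GENCODE 29 lengths, known for 98.6% of tested genes, lowess span 0.3), and, for lists, single libraries left out. For each count, other groupings of the same libraries were refitted, all 10 for pairs of groups and 50 drawn for the rest. No count column was left out.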

Results

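The 18 libraries came from Cal27, an established line of human oral squamous cell carcinoma (OSCC) from tongue, cultured for 24 hours in 3 media. The media were high-glucose DMEM, a glucose-deprived medium, and high-glucose DMEM with 5 mM 2-deoxyglucose (2-DG), a glucose analogue that blocks glycolysis and disturbs protein glycosylation. In each medium 3 libraries had 10 nM recombinant human calcitonin gene-related peptide (CGRP), a neuropeptide of sensory nerves, and 3 had control medium, as the series text reads its sample codes TG and capTG, which makes 6 groups of 3 independent repetitions. RNA sequencing gave 28.04M to 32.66M counts per library. Of these counts 4.37% ± 0.0412 (SD, n = 3) fell on mitochondrially encoded genes in the high-glucose control and 4.09% ± 0.164 in the deprived CGRP group. HSPA5, the main chaperone of the endoplasmic reticulum (ER), took 1.92% ± 0.0227 of counts in the deprived control and 0.0961% ± 9.69e-04 in the high-glucose control.

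The first principal component (68.7% of the variance) parted the deprived libraries from the rest. On the second (7.39%) 2 libraries stood apart from their groups, deprived CGRP 2 at 59.3 and 2-DG control 2 at 34.6, where their group mates lay between -14.8 and -9.78. Both were kept, and each count of changed genes is also given without them. Log2 fold changes are given ± SE and levels in CPM, counts scaled to library size, ± SD, with n = 3 libraries per group. Genes outside the naming rule, among them the members of lists with few changes, were chosen after their values were seen. Of each gene list the members that rose, fell and did not pass over all genes are counted first, then those that rose or fell in the same order adjusted over the list alone, then the median log2 fold change and the adjusted p of the list test (camera).

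**Figure D1:**
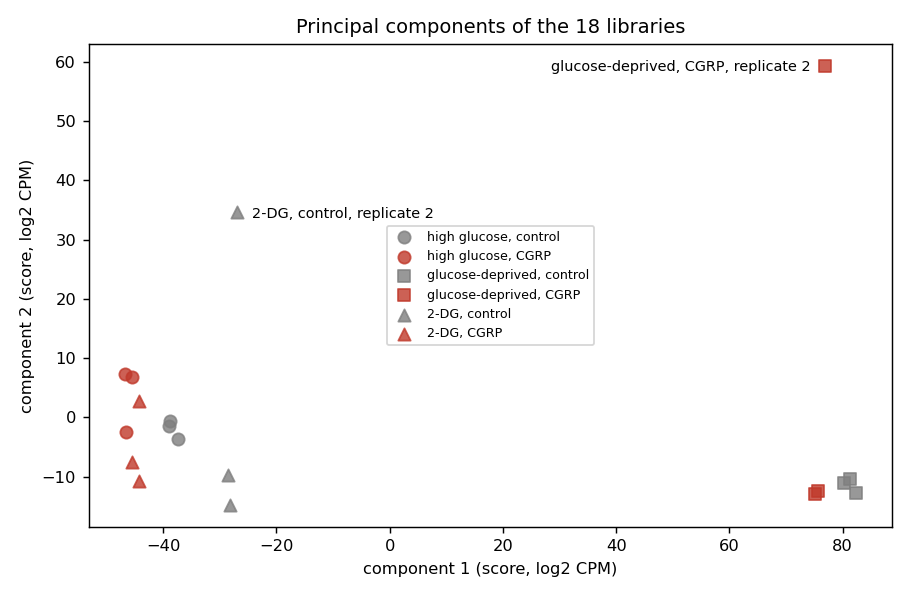
Scores of the 18 libraries on the first and the second principal component of log2 CPM, with grey for control, red for CGRP, and the marker shape for the medium. Deprived CGRP 2 (59.3) and 2-DG control 2 (34.6) lie above the other 16 libraries on the second component.

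CGRP in high glucose, set against its control, shows the response to the peptide in ordinary medium. CGRP lowered targets of ATF4, the transcription factor of the integrated stress response and of amino acid synthesis, along with inflammatory cytokines and AP-1 transcription factors. PSAT1, an enzyme of serine synthesis (ENSG00000135069), went from 338 ± 3.35 to 193 ± 2.72 CPM (SD, n = 3), a log2 fold change of -0.81 ± 0.05, adjusted p = 1.6e-07. IL1A, a cytokine that alerts neighbouring cells to damage, went from 467 ± 6.76 to 231 ± 4.20 CPM (-1.01 ± 0.04, adjusted p = 1.4e-09). CSF2, which encodes the growth factor GM-CSF, went from 23.8 ± 0.430 to 7.72 ± 0.485 CPM (-1.63 ± 0.11, adjusted p = 2.1e-07). LYPD1, which encodes a protein that modulates nicotinic receptors, rose from 4.08 ± 0.397 to 10.5 ± 0.173 CPM (1.36 ± 0.11, adjusted p = 2.6e-06).

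Of 18159 genes tested, 787 changed with CGRP in high glucose, 371 up and 416 down, and 34 rose and 33 fell by at least 2-fold. After LYPD1 the largest rises were AKR1B10 (1.22 ± 0.19), MAB21L4 (1.22 ± 0.17), NEFM (1.07 ± 0.10) and METTL7A (1.07 ± 0.18). NEFM encodes a neurofilament and AKR1B10 an aldo-keto reductase. Beside CSF2 the largest falls were INHBE (-2.14 ± 0.24), IL1RL1 (-1.70 ± 0.42), CHAC1 (-1.55 ± 0.14) and SPRY4 (-1.42 ± 0.26) (adjusted p 5.7e-06 to 0.027 for these 8 genes). SPRY4 is a feedback inhibitor of growth factor signalling and CHAC1 breaks down glutathione.

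Of 31 gene lists, 8 shifted up and 5 down with CGRP in high glucose. Another grouping of the libraries gave as many, as for deprivation, 2-DG and 2-DG against deprivation. Among ATF4 targets 16 of 28 fell, 0 rose and 12 did not pass (22 and 0 adjusted over the list alone, median -0.40, adjusted p = 5.7e-39). Among them were GDF15 (-1.01 ± 0.07), STC2 (-0.72 ± 0.06), TRIB3 (-0.60 ± 0.08) and ASNS (-1.18 ± 0.30) beside PSAT1. Among aminoacyl-tRNA synthetases, which charge tRNAs, 11 of 18 fell, 0 rose and 7 did not pass (13 and 1 adjusted over the list alone, median -0.23, adjusted p = 8.8e-16). These included GARS1 (-0.55) and MARS1 (-0.41). Among NF-kB inflammatory genes 6 of 19 fell, 0 rose and 13 did not pass (8 and 0 adjusted over the list alone, median -0.15, adjusted p = 4.0e-22). They included IL1B (-0.78). In the AP-1 family 6 of 11 fell, 0 rose and 5 did not pass (7 and 0 adjusted over the list alone, median -0.42, adjusted p = 1.6e-15). Among them were FOSL1 (-1.29) and JUN (-0.47). Among cAMP/CREB-responsive genes, a class that rising cAMP is known to induce, 6 of 20 fell, 0 rose and 14 did not pass (10 and 0 adjusted over the list alone, median -0.30, adjusted p = 4.9e-11). The fallers were FOSL1 (-1.29), INHBA (-1.17), EGR1 (-0.79), AREG (-0.57), NR4A1 (-0.54) and ATF3 (-0.42), and 5 genes of this list are also in the AP-1 list.

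Hypoxia-responsive genes moved the other way in high glucose: 8 of 16 rose, 1 fell and 7 did not pass (13 and 1 adjusted over the list alone, median 0.32, adjusted p = 9.2e-14). They included CA9 (0.66) and LOX (0.60), while the angiogenic factor VEGFA (-0.49) fell. Among interferon-stimulated genes 7 of 20 rose, 0 fell and 13 did not pass (13 and 0 adjusted over the list alone, median 0.25, adjusted p = 1.2e-13). These included IFIT1 (0.55) and MX2 (0.47). In glycolysis 6 of 20 rose, 1 fell and 13 did not pass (10 and 1 adjusted over the list alone, median 0.20, adjusted p = 2.0e-08). They included ALDOC (0.39) and PGAM1 (0.32) up and PFKM (-0.27) down. In cholesterol synthesis 6 of 23 rose, 0 fell and 17 did not pass (9 and 0 adjusted over the list alone, median 0.17, adjusted p = 4.3e-08). Among them were LSS (0.40) and MVK (0.36). The mitochondrially encoded genes that rose were MT-ND1 (0.38), MT-ND6 (0.34), MT-CYB (0.31) and MT-ND2 (0.26), and the list gave 4 of 13 rose, 0 fell and 9 did not pass (4 and 0 adjusted over the list alone, median 0.24, adjusted p = 7.8e-06). Of lysosome genes 2 of 25 rose, 0 fell and 23 did not pass (4 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.0093, adjusted p = 0.22 with an estimated correlation). They included CTSB (0.32).

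Markers of neurons also shifted up in high glucose: 2 of 6 rose, 0 fell and 4 did not pass (3 and 0 adjusted over the list alone, median 0.26, adjusted p = 5.5e-05), the risers being the neurofilament genes NEFM (1.07) and NEFL (0.88). Of leukocyte markers 1 rose and 0 fell of 3 (1 and 0 adjusted over the list alone, adjusted p = 0.070), the riser being CD14 (0.75), and of fibroblast markers 0 rose and 0 fell of 4 (0 and 0 adjusted over the list alone, adjusted p = 0.43). Markers of endothelial cells and of Schwann cells had 2 tested genes each and were not tested as lists. CDH5, the cadherin of endothelial cells, went from 22.8 ± 0.433 to 41.3 ± 0.694 CPM (SD, n = 3, log2 fold change 0.85 ± 0.09, adjusted p = 1.7e-05).

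Of CGRP receptor and ligand genes 0 rose and 0 fell of 6 (0 and 0 adjusted over the list alone, adjusted p = 0.41), and the receptor subunit CALCRL had 5.24 ± 0.726 CPM in control and 5.58 ± 1.06 with CGRP. Of autophagy machinery 0 rose and 1 fell of 36 (0 and 1 adjusted over the list alone, adjusted p = 0.34), the faller being the autophagy receptor SQSTM1. Of mTOR pathway genes 0 rose and 0 fell of 24 (0 and 0 adjusted over the list alone, adjusted p = 0.85), of Rap1 regulators 0 rose and 0 fell of 18 (0 and 0 adjusted over the list alone, adjusted p = 0.90) and of ER chaperone and ERAD genes 0 rose and 0 fell of 21 (0 and 0 adjusted over the list alone, adjusted p = 0.80). Among the other genes named in advance TXNIP (0.35 ± 0.06) rose and SQSTM1 (-0.36 ± 0.07) fell, while CALCRL (0.09 ± 0.18), RAMP1 (0.13 ± 0.17), ARRDC4 (0.21 ± 0.06), HSPA5 (0.12 ± 0.07), DDIT3 (-0.46 ± 0.23), SLC2A1 (0.11 ± 0.08), HK2 (0.05 ± 0.15), ULK1 (0.09 ± 0.05), MAP1LC3B (-0.05 ± 0.08) and MKI67 (-0.07 ± 0.22) did not pass.

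The count in high glucose was 3520 without the 2 libraries that stand apart, 3653 in a fit of only the 6 libraries compared, 474 with no low-count filter, and 487, 353 and 461 without high-glucose control 1, 2 and 3 in turn, and 443, 419 and 422 without high-glucose CGRP 1, 2 and 3 in turn. Of changed genes 47.1% rose with TMM, 52.1% with RLE factors and 51.9% with total-count scaling. IL1RL1 and ASNS lost the call without any 1 of high-glucose control 2 and 3 and high-glucose CGRP 1 to 3 (adjusted p 0.054 to 0.18, and 1.5e-04 to 0.18 over all alternatives). ARRDC4, HSPA5, DDIT3 and SLC2A1 passed both without the 2 libraries that stand apart, which are not in this comparison, and in the fit of the 6 libraries (adjusted p 1.7e-04 to 0.012). ARRDC4 also passed with the stricter filter, the length offset and DESeq2 (adjusted p 0.0054 to 0.037).

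CGRP in glucose-deprived medium, set against its control, shows the response to the peptide in starved cells. CGRP lowered inflammatory cytokines and raised targets of NRF2, the transcription factor of the antioxidant response. CX3CL1, a chemokine, went from 105 ± 5.86 to 40.9 ± 1.05 CPM (SD, n = 3, log2 fold change -1.36 ± 0.05, adjusted p = 1.4e-10). IL6, an inflammatory cytokine, went from 38.6 ± 2.08 to 15.2 ± 2.29 CPM (-1.35 ± 0.10, adjusted p = 1.6e-06). AKR1C2, an aldo-keto reductase, went from 41.8 ± 2.08 to 84.2 ± 6.30 CPM (1.01 ± 0.08, adjusted p = 2.7e-06). HMOX1, heme oxygenase (ENSG00000100292), went from 52.8 ± 6.85 to 93.6 ± 6.96 CPM (0.83 ± 0.08, adjusted p = 8.8e-06).

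In deprived medium 2354 genes changed with CGRP, 1159 up and 1195 down, and 199 rose and 42 fell by at least 2-fold. The largest rises were RCSD1 (1.94 ± 0.20), RBBP8NL (1.76 ± 0.26), SYT8 (1.75 ± 0.16) and ARNT2 (1.61 ± 0.19). RAB7B, a small GTPase of late endosomes, had 2 counts in the deprived control and 16 with CGRP, a ratio of 8.36 with a 95% counting interval from 1.96 to 74.9 (adjusted p = 0.016). Beside CX3CL1 the largest falls were EDN2 (-2.60 ± 0.32), ANGPTL4 (-2.55 ± 0.22), SLC28A3 (-1.43 ± 0.35) and HAS3 (-1.38 ± 0.18) (adjusted p 4.3e-06 to 0.013 for these 8 genes). EDN2 encodes an endothelin, ANGPTL4 an inhibitor of lipoprotein lipase and HAS3 a hyaluronan synthase. Deprived CGRP 2, which stands apart from its group mates, is among the 6 libraries of this comparison and of the lists that follow.

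Of 31 lists, 4 shifted up and 7 down with CGRP in deprived medium. Among NF-kB inflammatory genes 12 of 19 fell, 0 rose and 7 did not pass (14 and 0 adjusted over the list alone, median -0.51, adjusted p = 4.8e-20). These included IL1A (-0.77) and LIF (-0.73). Among NRF2 targets 8 of 19 rose, 0 fell and 11 did not pass (13 and 1 adjusted over the list alone, median 0.27, adjusted p = 2.4e-10). They included AKR1C3 (1.26), AKR1C1 (0.81) and GCLM (0.48). The AKR1C genes are close paralogs, whose shared reads leave their single values uncertain. In the AP-1 family 5 of 11 fell, 0 rose and 6 did not pass (5 and 0 adjusted over the list alone, median -0.18, adjusted p = 1.3e-04). Among them were ATF3 (-0.57), MAFF (-0.43) and JUN (-0.30). Among cAMP/CREB-responsive genes 5 of 20 fell, 1 rose and 14 did not pass (9 and 2 adjusted over the list alone, median -0.20, adjusted p = 0.0017). These included INHBA (-1.32) and AREG (-0.75) down and PPARGC1A (1.13) up. Among ATF4 targets 7 of 28 fell, 0 rose and 21 did not pass (10 and 0 adjusted over the list alone, median -0.16, adjusted p = 0.0030, adjusted p = 0.17 with an estimated correlation). They included STC2 (-0.37) and PPP1R15A (-0.29). Among aminoacyl-tRNA synthetases 4 of 18 fell, 0 rose and 14 did not pass (6 and 0 adjusted over the list alone, median -0.06, adjusted p = 0.015, adjusted p = 0.34 with an estimated correlation). They were MARS1 (-0.38), AARS1 (-0.24), LARS1 (-0.23) and VARS1 (-0.21).

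Proliferation genes were lower with CGRP in deprived medium. In cell cycle G2/M 6 of 20 fell, 0 rose and 14 did not pass (8 and 0 adjusted over the list alone, median -0.15, adjusted p = 0.0017). Among them were KIF20A (-0.39) and CCNA2 (-0.23). In DNA replication and G1/S 7 of 21 fell, 1 rose and 13 did not pass (9 and 1 adjusted over the list alone, median -0.14, adjusted p = 0.0035, adjusted p = 0.34 with an estimated correlation). These included CDC6 (-0.32) and MCM6 (-0.31). In cholesterol synthesis 6 of 23 rose, 1 fell and 16 did not pass (6 and 1 adjusted over the list alone, median 0.15, adjusted p = 0.0054, adjusted p = 0.063 with an estimated correlation). They included INSIG1 (0.44) and IDI1 (0.33). Markers of neurons shifted up: 2 of 6 rose, 0 fell and 4 did not pass (3 and 0 adjusted over the list alone, median 0.44, adjusted p = 0.0088). They were NEFM (1.31) and TRPV1 (0.42). Of leukocyte markers 1 rose and 0 fell of 3 (1 and 0 adjusted over the list alone, adjusted p = 0.60), CD14 being at 0.0444 ± 0.0502 CPM in control and 0.323 ± 0.111 with CGRP. Of fibroblast markers 2 rose and 0 fell of 4 (2 and 0 adjusted over the list alone, adjusted p = 0.080). They were COL1A2 (1.36) and PDGFRB (0.69).

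Of autophagy machinery 2 rose and 1 fell of 36 (1 and 1 adjusted over the list alone, adjusted p = 0.89). Among them were ATG4B (0.25) and WIPI2 (0.18) up and ULK1, the kinase that starts autophagy, down. Of mTOR pathway genes 2 rose and 0 fell of 24 (1 and 0 adjusted over the list alone, adjusted p = 0.73). They were CASTOR2 (0.83) and LAMTOR3 (0.23). Of Rap1 regulators 2 rose and 0 fell of 18 (2 and 0 adjusted over the list alone, adjusted p = 0.98). They were RASGRP2 (1.12) and SIPA1 (0.26). Of CGRP receptor and ligand genes 0 rose and 0 fell of 6 (0 and 0 adjusted over the list alone, adjusted p = 0.69) and of ER chaperone and ERAD genes 1 rose and 0 fell of 21 (1 and 0 adjusted over the list alone, adjusted p = 0.97). Among the genes named in advance TXNIP (-0.34 ± 0.07), ARRDC4 (-0.30 ± 0.08), ASNS (-0.76 ± 0.22), HK2 (-0.56 ± 0.15) and ULK1 (-0.19 ± 0.05) fell, while CALCRL (0.36 ± 0.22), RAMP1 (0.31 ± 0.20), HSPA5 (-0.07 ± 0.07), DDIT3 (0.42 ± 0.19), TRIB3 (-0.02 ± 0.08), SLC2A1 (-0.14 ± 0.08), SQSTM1 (0.17 ± 0.07), MAP1LC3B (0.03 ± 0.07) and MKI67 (-0.39 ± 0.23) did not pass.

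The count in deprived medium was 5307 without the 2 libraries that stand apart, 141 in a fit of only the 6 libraries compared, which lost 21 calls of named genes (adjusted p 0.059 to 0.30), and 1463 with no low-count filter. It was 1282, 1340 and 1382 without deprived control 1, 2 and 3 in turn, and total-count scaling gave 1467 up and 750 down. SLC28A3 lost the call without any 1 of deprived control 1 and deprived CGRP 3 (adjusted p 0.055 to 0.062, and 6.0e-04 to 0.13 over all alternatives). ASNS lost the call without any 1 of deprived control 1 and 3 and deprived CGRP 2 and with total-count scaling (adjusted p 0.0502 to 0.11, and 0.0082 to 0.22 over all alternatives). HK2 lost the call without any 1 of deprived control 1 to 3 and with no low-count filter and total-count scaling (adjusted p 0.0504 to 0.085, and 7.4e-04 to 0.28 over all alternatives). ARRDC4 lost the call without any 1 of deprived control 2 and 3 and deprived CGRP 1 and 2 and with no low-count filter, total-count scaling, both libraries that stand apart left out and the length offset (adjusted p 0.0503 to 0.096, and 0.0038 to 0.30 over all alternatives). ULK1 lost the call without any 1 of deprived control 2 and 3 and deprived CGRP 3 and with no low-count filter and total-count scaling (adjusted p 0.057 to 0.14, and 0.0025 to 0.26 over all alternatives). RAB7B lost the call without any 1 of deprived control 3 and deprived CGRP 1 (adjusted p 0.051 to 0.064, and 0.0020 to 0.064 over all alternatives). CCNA2 lost the call with no low-count filter and the length offset (adjusted p 0.067 to 0.077, and 0.0030 to 0.21 over all alternatives). Aminoacyl-tRNA synthetases lost the call without deprived CGRP 3 (adjusted p = 0.074, and 6.9e-04 to 0.34 over all alternatives). HSPA5, SQSTM1 and TRIB3 passed without the 2 libraries that stand apart (adjusted p 2.4e-05 to 0.0080), HSPA5 also without deprived CGRP 2 (adjusted p = 0.047), and SQSTM1 with the stricter filter and total-count scaling (adjusted p 0.022 to 0.043).

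CGRP in 2-DG medium, set against its control, shows the response to the peptide under a block of glycolysis. CGRP lowered ER chaperones together with ATF4 targets, and raised cholesterol synthesis and mitotic genes. HSPA5 (ENSG00000044574) went from 2267 ± 148 to 1393 ± 44.4 CPM (SD, n = 3, log2 fold change -0.70 ± 0.07, adjusted p = 9.6e-06), where the high-glucose control had 923 ± 4.11 CPM. FOSL1, an AP-1 subunit, went from 98.9 ± 10.3 to 32.3 ± 1.29 CPM (-1.62 ± 0.09, adjusted p = 1.7e-08). PSAT1 went from 420.0 ± 17.1 to 192 ± 3.12 CPM (-1.13 ± 0.05, adjusted p = 4.3e-09). INSIG1, which holds back sterol synthesis, went from 146 ± 2.60 to 208 ± 5.72 CPM (0.51 ± 0.06, adjusted p = 2.3e-05).

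In 2-DG medium 2216 genes changed with CGRP, 964 up and 1252 down, and 115 rose and 99 fell by at least 2-fold. The largest rises were MAB21L4 (1.68 ± 0.19), METTL7A (1.47 ± 0.18), LYPD1 (1.41 ± 0.11), CD34 (1.31 ± 0.18) and EDN2 (1.30 ± 0.29). Beside FOSL1 the largest falls were INHBE (-2.81 ± 0.22), CSF2 (-1.86 ± 0.10), SPRR1A (-1.59 ± 0.21) and SPRY4 (-1.52 ± 0.22) (adjusted p 1.4e-08 to 0.0074 for these 9 genes). INHBE encodes an activin subunit and SPRR1A a cornified envelope protein whose paralogs share sequence with it. 2-DG control 2, which stands apart from its group mates, is among the 6 libraries of this comparison and of the lists that follow.

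Of 31 lists, 8 shifted up and 8 down with CGRP in 2-DG medium. Among ATF4 targets 19 of 28 fell, 0 rose and 9 did not pass (20 and 0 adjusted over the list alone, median -0.54, adjusted p = 8.7e-33). These included GDF15 (-1.09) and STC2 (-0.93). Among ER chaperone and ERAD genes 17 of 21 fell, 0 rose and 4 did not pass (18 and 0 adjusted over the list alone, median -0.47, adjusted p = 7.5e-24). They included HYOU1 (-0.75) and PDIA4 (-0.46). Among aminoacyl-tRNA synthetases 12 of 18 fell, 0 rose and 6 did not pass (13 and 1 adjusted over the list alone, median -0.29, adjusted p = 5.3e-20). Among them were WARS1 (-0.75) and GARS1 (-0.68). In the AP-1 family 6 of 11 fell, 0 rose and 5 did not pass (7 and 0 adjusted over the list alone, median -0.32, adjusted p = 4.2e-11). These included JUN (-0.68) and MAFF (-0.58). Among NF-kB inflammatory genes 5 of 19 fell, 0 rose and 14 did not pass (7 and 0 adjusted over the list alone, median -0.11, adjusted p = 4.3e-09). They were CSF2 (-1.86), CSF3 (-1.43), LIF (-0.98), IL1A (-0.76) and IL1B (-0.53). Among cAMP/CREB-responsive genes 6 of 20 fell, 0 rose and 14 did not pass (7 and 0 adjusted over the list alone, median -0.07, adjusted p = 1.7e-04). They included INHBA (-1.16) and EGR1 (-0.98). In keratinocyte differentiation 3 of 9 fell, 1 rose and 5 did not pass (4 and 1 adjusted over the list alone, median -0.49, adjusted p = 0.0038, adjusted p = 0.058 with an estimated correlation). Among them were SPRR1A (-1.59), SPRR1B (-1.10) and KRT80 (-0.49) down and TGM1 (0.51) up.

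The upward shifts in 2-DG medium led with cholesterol synthesis, where 14 of 23 rose, 0 fell and 9 did not pass (18 and 0 adjusted over the list alone, median 0.26, adjusted p = 5.3e-13). These included MSMO1 (0.42) and MVK (0.52). In cell cycle G2/M 11 of 20 rose, 0 fell and 9 did not pass (14 and 0 adjusted over the list alone, median 0.23, adjusted p = 1.5e-09). They included KIF20A (0.55) and TPX2 (0.30). Among hypoxia-responsive genes 10 of 16 rose, 2 fell and 4 did not pass (12 and 2 adjusted over the list alone, median 0.30, adjusted p = 8.0e-06). Among them were EGLN1 (0.58) and CA9 (0.52) up and VEGFA (-0.62) and P4HA2 (-0.29) down. In glycolysis 8 of 20 rose, 1 fell and 11 did not pass (11 and 1 adjusted over the list alone, median 0.17, adjusted p = 2.1e-05, adjusted p = 0.062 with an estimated correlation). These included ALDOC (0.54), PGAM1 (0.46) and ENO2 (0.41). Among interferon-stimulated genes 5 of 20 rose, 0 fell and 15 did not pass (6 and 0 adjusted over the list alone, median 0.13, adjusted p = 1.4e-04, adjusted p = 0.079 with an estimated correlation). They were OAS1 (0.42), IFIT1 (0.40), IFI44L (0.39), MX2 (0.35) and MX1 (0.24). Markers of other cell types also shifted up: of neurons 1 of 6 rose, 0 fell and 5 did not pass (1 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.044, adjusted p = 0.084 with an estimated correlation), the riser being NEFM (0.98), and of fibroblasts 1 of 4 rose, 0 fell and 3 did not pass (1 and 0 adjusted over the list alone, median 0.33, adjusted p = 0.028, adjusted p = 0.21 with an estimated correlation), the riser being COL1A1 (0.48). Of leukocyte markers 1 of 3 rose, 0 fell and 2 did not pass (2 and 0 adjusted over the list alone, adjusted p = 0.0052, adjusted p = 0.052 with an estimated correlation), the riser being PTPRC, at 0.0110 ± 0.0190 CPM in control and 0.641 ± 0.160 with CGRP.

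Of autophagy machinery 1 rose and 3 fell of 36 (1 and 3 adjusted over the list alone, adjusted p = 0.92). They included SQSTM1 (-0.56), VMP1 (-0.25) and WIPI1 (-0.23) down and ULK1 up. Of mTOR pathway genes 1 rose and 0 fell of 24 (1 and 0 adjusted over the list alone, adjusted p = 0.73), the riser being CASTOR2 (0.40). Of Rap1 regulators 2 rose and 2 fell of 18 (4 and 2 adjusted over the list alone, adjusted p = 0.17). Among them were RASGRP2 (0.72) and SIPA1 (0.28) up and RAPGEF3 (-0.60) and RAP1GAP (-0.21) down. Of partial EMT genes 3 rose and 4 fell of 15 (4 and 5 adjusted over the list alone, adjusted p = 0.17), with a median of -0.01, a mean of 0.07 and a downward test. Of CGRP receptor and ligand genes 0 rose and 1 fell of 6 (1 and 1 adjusted over the list alone, adjusted p = 0.91). Among the other genes named in advance TXNIP (0.33 ± 0.06) and ULK1 (0.30 ± 0.05) rose and TRIB3 (-1.05 ± 0.08) and SQSTM1 (-0.56 ± 0.07) fell, while CALCRL (0.52 ± 0.18), RAMP1 (-0.10 ± 0.17), ARRDC4 (-0.02 ± 0.06), DDIT3 (-0.45 ± 0.22), ASNS (-0.69 ± 0.30), SLC2A1 (0.09 ± 0.08), HK2 (0.06 ± 0.15), MAP1LC3B (-0.06 ± 0.08) and MKI67 (0.39 ± 0.23) did not pass.

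The count in 2-DG medium was 5249 without the 2 libraries that stand apart, 1194 in a fit of only the 6 libraries compared, and 1466 and 1447 without 2-DG CGRP 2 and 3 in turn. Of changed genes 43.5% rose with TMM, 51.1% with RLE factors and 57.0% with total-count scaling. ASNS passed without the 2 libraries that stand apart (adjusted p = 0.0064). CALCRL passed without 2-DG control 1 (0.68, adjusted p = 0.044) and with DESeq2 (0.55, adjusted p = 0.047), 0.044 to 0.26 over all alternatives. Markers of neurons lost the call with both libraries that stand apart left out and the length offset (adjusted p 0.079 to 0.080, and 1.1e-04 to 0.084 over all alternatives). Markers of fibroblasts lost the call with both libraries that stand apart left out (adjusted p = 0.079, and 0.0048 to 0.21 over all alternatives).

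**Figure D2:**
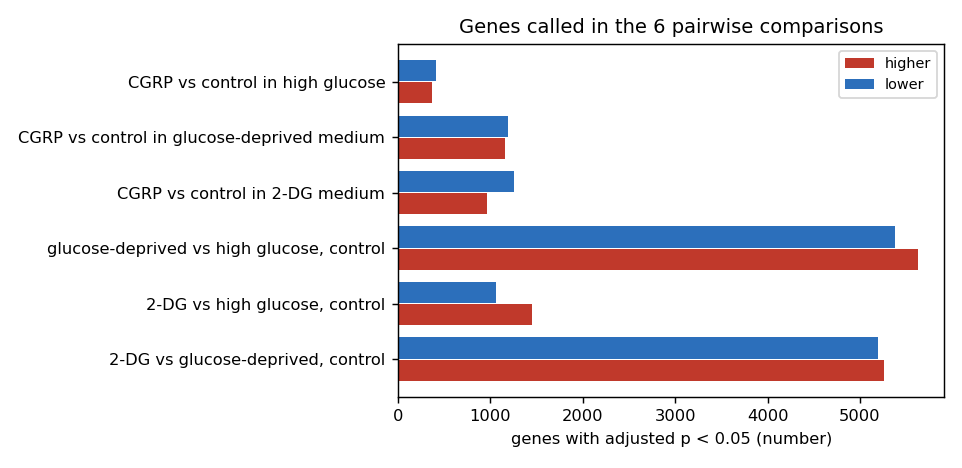
Number of genes with adjusted p under 0.05 (x axis), up and down, in each of the 6 pairwise comparisons (y axis). Glucose deprivation against high glucose changed 11011 genes and CGRP in high glucose 787.

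The genes that CGRP changed in the separate media overlapped, in comparisons that share no library. In high glucose and 2-DG medium 245 genes rose in both and 329 fell in both, where independent changes would give 19.7 and 28.7, and 4 went opposite ways. In high glucose and deprived medium 177 rose and 224 fell in both (23.7 and 27.4 if independent), and 24 went opposite ways. In deprived and 2-DG medium 302 rose and 431 fell in both (61.5 and 82.4 if independent), and 77 went opposite ways. Across 12879 genes, which are not independent replicates, the log2 fold changes in high glucose correlated with those in 2-DG medium (Pearson r = 0.607, Spearman rho = 0.490) and in deprived medium (r = 0.470, rho = 0.473), and those in deprived and 2-DG medium with each other (r = 0.318, rho = 0.224).

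Averaged over the 3 media, CGRP changed 3883 genes, 1802 up and 2081 down. The largest rises were RCSD1 (1.36 ± 0.08), MAB21L4 (1.35 ± 0.10), LYPD1 (1.19 ± 0.08), LINC01559 (1.15 ± 0.11) and NEFM (1.12 ± 0.07), and the largest falls ANGPTL4 (-1.72 ± 0.11), CSF2 (-1.52 ± 0.06), SPRY4 (-1.28 ± 0.13), INHBA (-1.22 ± 0.13) and FOSL1 (-1.13 ± 0.05) (adjusted p 1.7e-10 to 4.8e-06). Of 31 lists 7 shifted up and 7 down. Among ATF4 targets 21 of 28 fell, 0 rose and 7 did not pass (22 and 0 adjusted over the list alone, median -0.35, adjusted p = 1.3e-30), and among NF-kB inflammatory genes 11 of 19 fell, 0 rose and 8 did not pass (13 and 1 adjusted over the list alone, median -0.22, adjusted p = 1.9e-22). Of fibroblast markers 3 of 4 rose, 0 fell and 1 did not pass (3 and 0 adjusted over the list alone, median 0.27, adjusted p = 0.043, adjusted p = 0.29 with an estimated correlation). They were COL1A2 (0.61), PDGFRB (0.31) and COL1A1 (0.22). The averaged count was 7209 without the 2 libraries that stand apart. Of changed genes 46.4% rose with TMM, 52.3% with RLE factors and 60.4% with total-count scaling. Markers of fibroblasts lost the call without any 1 of high-glucose control 2, high-glucose CGRP 1, deprived control 3 and deprived CGRP 1 and with the length offset (adjusted p 0.051 to 0.13, and 0.0021 to 0.29 over all alternatives).

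**Figure D3:**
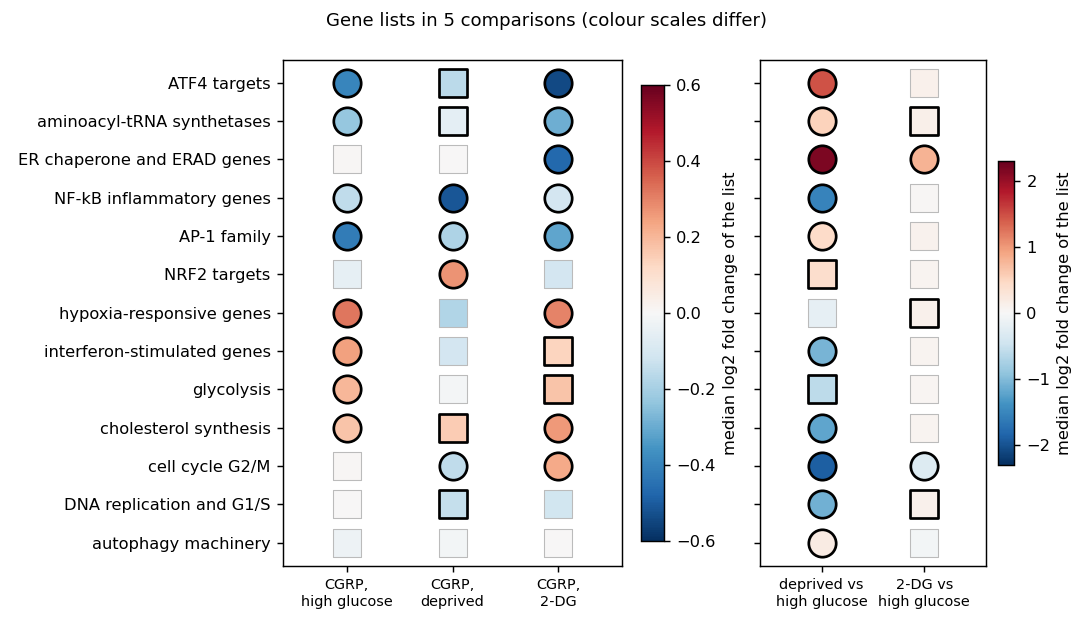
Median log2 fold change (colour) of 13 gene lists (y axis) in 3 CGRP comparisons and 2 media comparisons (x axis), where a black edge marks a camera adjusted p under 0.05 and a circle, in place of a square, a call that also holds with an estimated correlation. The median of ER chaperone and ERAD genes is -0.47 with CGRP in 2-DG medium and 2.16 in deprivation, on a wider colour scale.

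The interaction of CGRP with deprivation tests whether the effect of CGRP in deprived medium differed from that in high glucose. It differed in 282 genes, 164 with a higher and 118 with a lower effect in deprived medium. INHBE went from 26.5 ± 2.01 to 30.9 ± 2.62 CPM (SD, n = 3) in deprived medium and from 1.35 ± 0.0633 to 0.302 ± 0.0991 CPM in high glucose, a difference in log2 fold change of 2.37 ± 0.27, adjusted p = 2.5e-04. STC1, a glycoprotein hormone induced in hypoxia, went from 2.56 ± 0.372 to 1.08 ± 0.452 CPM and from 18.4 ± 0.799 to 30.6 ± 2.61 CPM, a difference of -1.96 ± 0.23, adjusted p = 3.2e-04. The other largest differences were FSD1 (1.51 ± 0.21), FLRT1 (1.51 ± 0.27), FGF1 (1.43 ± 0.12) and ARNT2 (1.32 ± 0.22) upward and EDN2 (-2.71 ± 0.42), TCAF2 (-1.65 ± 0.21), ANGPTL4 (-1.38 ± 0.28) and SPRY1 (-1.25 ± 0.20) downward (adjusted p 1.3e-05 to 0.019).

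Of 31 lists, the effect of CGRP was higher in deprived medium in 5 and lower in 7, counted below as rises and falls of the difference. Deprived CGRP 2, which stands apart, is among the 12 libraries, and without it 19 lists differed. Of NRF2 targets 7 of 19 rose, 0 fell and 12 did not pass (12 and 0 adjusted over the list alone, median 0.36, adjusted p = 2.8e-18). These included AKR1C2 (1.08), GCLM (0.79) and HMOX1 (0.77). Of ATF4 targets 7 of 28 rose, 0 fell and 21 did not pass (15 and 0 adjusted over the list alone, median 0.33, adjusted p = 6.2e-15). They included CHAC1 (1.29), GDF15 (1.17) and PSAT1 (0.63). Of hypoxia-responsive genes 6 of 16 fell, 0 rose and 10 did not pass (11 and 1 adjusted over the list alone, median -0.38, adjusted p = 4.0e-16). Among them were EGLN3 (-0.93) and LOX (-0.82). Of interferon-stimulated genes 7 of 20 fell, 0 rose and 13 did not pass (10 and 0 adjusted over the list alone, median -0.31, adjusted p = 6.2e-15). These included OASL (-0.66) and IFI44L (-0.66).

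The count was 2500 without the 2 libraries that stand apart (43.3% higher) and 275 with total-count scaling (70.5%). It was 164 in a fit of only the 4 groups compared, 163 with no low-count filter and 507 with DESeq2. Leaving out 1 high-glucose library gave 176, 164 and 162 (control 1 to 3) and 164, 170 and 175 (CGRP 1 to 3). Deprived ones gave 173 and 177 (control 1 and 2) and 582 (CGRP 2). ANGPTL4 lost the call without any 1 of high-glucose control 2 and 3, high-glucose CGRP 1 and 3 and deprived control 1 and with no low-count filter and a fit of only the groups compared (adjusted p 0.0501 to 0.088, and 5.9e-05 to 0.088 over all alternatives).

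The interaction of CGRP with 2-DG tests whether the effect of CGRP in 2-DG medium differed from that in high glucose. It differed in 71 genes, 22 with a higher and 49 with a lower effect in 2-DG medium. AGR2, a protein disulfide isomerase of the ER, went from 44.9 ± 8.61 to 21.2 ± 1.82 CPM (SD, n = 3) in 2-DG medium and from 7.29 ± 0.391 to 12.2 ± 0.680 CPM in high glucose, a difference of -1.82 ± 0.23, adjusted p = 0.0023. The difference for HSPA5 was -0.82 ± 0.10, adjusted p = 0.0020, and for LAMB3, a laminin chain, -0.73 ± 0.07, adjusted p = 2.7e-04. The others were CTHRC1 (-0.81 ± 0.16) and NUCB2 (-0.71 ± 0.11) downward and HCG27 (0.85 ± 0.17), TEC (0.78 ± 0.15), TRAV8-1 (0.61 ± 0.13), CCNG2 (0.56 ± 0.10) and CYP1A1 (0.52 ± 0.09) upward (adjusted p 0.015 to 0.049).

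Of 31 lists, the effect of CGRP was higher in 2-DG medium in 2 and lower in 6. Of ER chaperone and ERAD genes 5 of 21 fell, 0 rose and 16 did not pass (18 and 0 adjusted over the list alone, median -0.48, adjusted p = 6.1e-39). They were HSPA5 (-0.82), HYOU1 (-0.62), DNAJB11 (-0.54), DNAJB9 (-0.48) and PDIA4 (-0.43). In cell cycle G2/M 2 of 20 rose, 0 fell and 18 did not pass (9 and 0 adjusted over the list alone, median 0.23, adjusted p = 1.0e-12). In cholesterol synthesis 0 of 23 rose, 0 fell and 23 did not pass (0 and 0 adjusted over the list alone, median 0.14, adjusted p = 4.7e-04). Of mitochondrially encoded genes 0 of 13 fell, 0 rose and 13 did not pass (4 and 0 adjusted over the list alone, median -0.25, adjusted p = 1.9e-05). 2-DG control 2, which stands apart, is among the 12 libraries behind these lists.

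The count was 1092 without the 2 libraries that stand apart (39.2% higher) and 63 with total-count scaling (44.4%). It was 142 in a fit of only the 4 groups compared, 30 with no low-count filter (30%) and 227 with DESeq2. Leaving out 1 high-glucose library gave 13, 17 and 17 (control 1 to 3) and 17, 19 and 16 (CGRP 1 to 3). 2-DG ones gave 23 and 20 (control 1 and 3) and 19, 15 and 18 (CGRP 1 to 3). Of the 10 named genes AGR2, HSPA5 and LAMB3 kept their calls in all of these settings. Of the 12 libraries compared, HCG27, TEC and TRAV8-1 lost the call without any 1 (adjusted p 0.065 to 0.16, and 1.6e-04 to 0.16 over all alternatives). CTHRC1 lost the call without any but 2-DG control 1 (adjusted p 0.074 to 0.13, and 3.6e-04 to 0.13 over all alternatives). CYP1A1 lost the call without any but 2-DG control 2, 2-DG control 3 and high-glucose CGRP 2 (adjusted p 0.053 to 0.073, and 2.8e-05 to 0.073 over all alternatives). CCNG2 lost the call without any but 2-DG CGRP 3, 2-DG control 1, 2-DG control 2, high-glucose CGRP 2 and high-glucose control 3 (adjusted p 0.055 to 0.076, and 3.5e-06 to 0.076 over all alternatives). NUCB2 lost the call without any 1 of high-glucose control 1 and 2, high-glucose CGRP 3 and 2-DG CGRP 2 (adjusted p 0.055 to 0.073, and 3.4e-12 to 0.073 over all alternatives).

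Glucose-deprived against high-glucose control shows what loss of glucose did without CGRP. Stress-response genes of the ER rose and genes of proliferation and sterol synthesis fell. HSPA5 went from 923 ± 4.11 to 20596 ± 227 CPM (SD, n = 3, log2 fold change 4.48 ± 0.08, adjusted p = 7.4e-16). DDIT3, the stress factor CHOP, went from 10.3 ± 0.633 to 256 ± 8.91 CPM (4.63 ± 0.23, adjusted p = 4.4e-11). TXNIP (ENSG00000265972), which brakes glucose uptake, went from 574 ± 28.3 to 13.4 ± 0.257 CPM (-5.42 ± 0.07, adjusted p = 1.6e-17). MKI67, a marker of dividing cells, went from 588 ± 25.3 to 118 ± 3.03 CPM (-2.31 ± 0.24, adjusted p = 3.2e-07).

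With deprivation 11011 genes changed, 5633 up and 5378 down, and 1517 rose and 2258 fell by at least 2-fold. The largest rises were RAB39B (7.76 ± 0.26), CMKLR2 (7.20 ± 0.24), SCN9A (5.19 ± 0.22), LURAP1L (4.86 ± 0.10) and AGR2 (4.85 ± 0.18). SCN9A encodes a sodium channel of pain-sensing neurons and CMKLR2 a chemerin receptor. RAB7B was lower, with 224 counts in high glucose and 2 in deprived medium, a ratio of 109 with a 95% counting interval from 29.8 to 906 (adjusted p = 7.4e-10). The other large falls were METTL7A (-5.59 ± 0.39), CD34 (-5.19 ± 0.36) and MAP2K6 (-5.18 ± 0.34) (adjusted p 1.3e-15 to 3.1e-09 for these 8 genes). Among the genes named in advance JUN (0.93 ± 0.05), ASNS (1.60 ± 0.23), TRIB3 (3.72 ± 0.09), SLC2A1 (0.82 ± 0.08), HK2 (1.01 ± 0.15), ULK1 (0.18 ± 0.05), SQSTM1 (1.82 ± 0.07) and MAP1LC3B (2.17 ± 0.08) rose and CALCRL (-1.27 ± 0.20), RAMP1 (-1.42 ± 0.19) and ARRDC4 (-2.32 ± 0.07) fell.

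Of 31 lists, 7 shifted up and 9 down with deprivation. Among ER chaperone and ERAD genes 21 of 21 rose, 0 fell and 0 did not pass (21 and 0 adjusted over the list alone, median 2.16, adjusted p = 1.9e-44). They included HERPUD1 (3.31) and PDIA4 (2.43). Among ATF4 targets 25 of 28 rose, 2 fell and 1 did not pass (25 and 2 adjusted over the list alone, median 1.47, adjusted p = 1.5e-29). Among them were ATF3 (2.78) and SESN2 (2.77). Among aminoacyl-tRNA synthetases 15 of 18 rose, 1 fell and 2 did not pass (15 and 2 adjusted over the list alone, median 0.53, adjusted p = 2.0e-08). These included WARS1 (2.40) and GARS1 (1.60). In autophagy machinery 19 of 36 rose, 3 fell and 14 did not pass (19 and 3 adjusted over the list alone, median 0.19, adjusted p = 0.0016). They included WIPI1 (2.44), MAP1LC3B (2.17) and SQSTM1 (1.82) up and GABARAPL2 (-0.63), PIK3R4 (-0.61) and ATG4A (-0.22) down. Among NRF2 targets 12 of 19 rose, 5 fell and 2 did not pass (12 and 6 adjusted over the list alone, median 0.41, adjusted p = 0.0031, adjusted p = 0.19 with an estimated correlation). Among them were SLC7A11 (2.42) and HMOX1 (2.36) up and AKR1B10 (-2.68) down. In the AP-1 family 8 of 11 rose, 3 fell and 0 did not pass (8 and 3 adjusted over the list alone, median 0.44, adjusted p = 0.0040), with falls of FOS (-1.88), JUNB (-0.90) and FOSL2 (-0.60).

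The downward shifts with deprivation led with cell cycle G2/M, where 20 of 20 fell, 0 rose and 0 did not pass (20 and 0 adjusted over the list alone, median -1.90, adjusted p = 3.5e-36). These included KIF20A (-2.74) and CCNA2 (-2.13). In DNA replication and G1/S 20 of 21 fell, 1 rose and 0 did not pass (20 and 1 adjusted over the list alone, median -1.10, adjusted p = 6.9e-17). They included RRM2 (-2.18) and MCM6 (-1.94). In cholesterol synthesis 21 of 23 fell, 0 rose and 2 did not pass (21 and 0 adjusted over the list alone, median -1.21, adjusted p = 2.8e-22). Among them were INSIG1 (-2.92) and MSMO1 (-1.74). Among interferon-stimulated genes 16 of 20 fell, 0 rose and 4 did not pass (16 and 0 adjusted over the list alone, median -1.07, adjusted p = 5.9e-13). They included OAS1 (-2.14) and IFIT3 (-1.75). Among NF-kB inflammatory genes 13 of 19 fell, 6 rose and 0 did not pass (13 and 6 adjusted over the list alone, median -1.53, adjusted p = 8.9e-08). Among them were IL1B (-2.48) and CXCL1 (-2.45) down and IL6 (2.94) and CXCL2 (1.31) up. Among heat shock genes 8 of 10 fell, 0 rose and 2 did not pass (8 and 0 adjusted over the list alone, median -0.66, adjusted p = 1.1e-04, adjusted p = 0.14 with an estimated correlation). These included HSP90AA1 (-2.18) and HSPB1 (-1.60). In glycolysis 15 of 20 fell, 4 rose and 1 did not pass (16 and 4 adjusted over the list alone, median -0.60, adjusted p = 2.8e-04, adjusted p = 0.13 with an estimated correlation). They included ALDOC (-1.95) and LDHA (-1.40) down and HK2 (1.01), SLC2A1 (0.82), PFKFB4 (0.58) and SLC16A3 (0.20) up.

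Markers of fibroblasts moved with deprivation as well: 4 of 4 fell, 0 rose and 0 did not pass (4 and 0 adjusted over the list alone, median -1.77, adjusted p = 0.018, adjusted p = 0.18 with an estimated correlation). They were LUM (-3.02), COL1A2 (-2.33), COL1A1 (-1.21) and PDGFRB (-0.95). Of neuron markers 4 rose and 2 fell of 6 (4 and 2 adjusted over the list alone, adjusted p = 0.090). Among them were SCN9A (5.19) and SYT1 (1.21) up and NEFM (-2.83) and NEFL (-1.39) down. The lists that did not shift included p53 targets, where 7 rose and 3 fell of 14 (7 and 3 adjusted over the list alone, adjusted p = 0.23), and mTOR pathway genes, where 12 rose and 2 fell of 24 (12 and 2 adjusted over the list alone, adjusted p = 0.36). Of partial EMT genes 6 rose and 6 fell of 15 (6 and 6 adjusted over the list alone, adjusted p = 0.37), with a median of 0.12 beside a downward test. Of Rap1 regulators 4 rose and 6 fell of 18 (4 and 6 adjusted over the list alone, adjusted p = 0.44), with a median of 0.05 and a mean of -0.19.

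The count with deprivation was 13377 without the 2 libraries that stand apart, and total-count scaling, which moved the median log2 fold change of all genes to -0.13, gave 4161 up and 6784 down. ULK1 lost the call without deprived control 3 and with no low-count filter and total-count scaling (adjusted p 0.059 to 0.72, and 6.7e-05 to 0.72 over all alternatives). Markers of fibroblasts lost the call with both libraries that stand apart left out (adjusted p = 0.093, and 2.6e-08 to 0.18 over all alternatives).

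2-DG against high-glucose control shows what the inhibitor did without CGRP. ER chaperones rose and G2/M genes fell. HSPA5 went from 923 ± 4.11 to 2267 ± 148 CPM (SD, n = 3, log2 fold change 1.30 ± 0.07, adjusted p = 2.3e-08). AGR2 went from 7.29 ± 0.391 to 44.9 ± 8.61 CPM (2.62 ± 0.17, adjusted p = 9.0e-08). LAMB3 went from 842 ± 18.5 to 1524 ± 43.9 CPM (0.86 ± 0.05, adjusted p = 4.8e-08). KIF20A, a mitotic kinesin, went from 143 ± 2.87 to 95 ± 1.55 CPM (-0.59 ± 0.05, adjusted p = 1.7e-06).

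With 2-DG 2513 genes changed, 1451 up and 1062 down, and 55 rose and 121 fell by at least 2-fold. The other large rises were BHLHA15 (1.59 ± 0.32), MANF (1.29 ± 0.14) and CSF2 (1.25 ± 0.10), of which MANF is a secreted ER stress factor. The largest falls were EDN2 (-1.28 ± 0.29), TJP3 (-1.25 ± 0.17), SH2D3C (-1.14 ± 0.15), LINC01285 (-1.13 ± 0.21) and LINC01843 (-1.11 ± 0.18) (adjusted p 4.8e-07 to 0.0075 for these 8 genes). 2-DG control 2, which stands apart, is among the 6 libraries of this comparison and of the lists that follow. Among the genes named in advance JUN (0.38 ± 0.05), TXNIP (0.30 ± 0.06), ARRDC4 (0.81 ± 0.06), TRIB3 (0.65 ± 0.08) and SQSTM1 (0.41 ± 0.07) rose and ULK1 (-0.45 ± 0.05) fell, while CALCRL (-0.28 ± 0.19), RAMP1 (0.32 ± 0.17), DDIT3 (0.40 ± 0.22), ASNS (-0.23 ± 0.27), SLC2A1 (0.10 ± 0.08), HK2 (-0.10 ± 0.15), MAP1LC3B (-0.09 ± 0.08) and MKI67 (-0.45 ± 0.23) did not pass.

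Of 31 lists, 7 shifted up and 1 down with 2-DG. Among ER chaperone and ERAD genes 20 of 21 rose, 0 fell and 1 did not pass (21 and 0 adjusted over the list alone, median 0.80, adjusted p = 1.5e-68). These included HERPUD1 (1.05) and PDIA4 (0.91). In cell cycle G2/M 13 of 20 fell, 0 rose and 7 did not pass (15 and 0 adjusted over the list alone, median -0.32, adjusted p = 2.6e-13). They included TPX2 (-0.38) and BUB1 (-0.46). In DNA replication and G1/S, unlike G2/M, 7 of 21 rose, 1 fell and 13 did not pass (7 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.0092, adjusted p = 0.46 with an estimated correlation), with CDC6 (0.41) and MCM3 (0.27) up. In partial EMT genes 7 of 15 rose, 0 fell and 8 did not pass (7 and 0 adjusted over the list alone, median 0.19, adjusted p = 0.0015). Among them were MMP1 (0.63) and CDH2 (0.26). Among aminoacyl-tRNA synthetases 5 of 18 rose, 0 fell and 13 did not pass (9 and 0 adjusted over the list alone, median 0.14, adjusted p = 4.1e-04, adjusted p = 0.18 with an estimated correlation). These included WARS1 (0.53) and HARS1 (0.23). Among hypoxia-responsive genes 5 of 16 rose, 1 fell and 10 did not pass (6 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.0092, adjusted p = 0.18 with an estimated correlation). Among them were VEGFA (0.58) and P4HA2 (0.53). Of metallothioneins 2 of 5 rose, 0 fell and 3 did not pass (2 and 0 adjusted over the list alone, median 0.69, adjusted p = 0.033, adjusted p = 0.49 with an estimated correlation). They were MT1X (1.01) and MT1E (0.92). Of cytosolic ribosomal proteins 0 of 75 rose, 0 fell and 75 did not pass (0 and 0 adjusted over the list alone, median 0.25, adjusted p = 6.6e-04, adjusted p = 0.74 with an estimated correlation). Of ATF4 targets 7 rose and 3 fell of 28 (10 and 3 adjusted over the list alone, adjusted p = 0.054), and of autophagy machinery 2 rose and 4 fell of 36 (2 and 4 adjusted over the list alone, adjusted p = 0.054).

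The count with 2-DG was 5997 without the 2 libraries that stand apart, 1551 in a fit of only the 6 libraries compared, and 1631 and 1593 without high-glucose control 1 and 3 in turn. Total-count scaling gave 961 up and 1563 down. MT1X lost the call without any 1 of high-glucose control 1 and 2 and 2-DG control 2 and with no low-count filter and a fit of only the groups compared (adjusted p 0.10 to 0.20, and 0.012 to 0.20 over all alternatives). HARS1 lost the call without any 1 of high-glucose control 3 and 2-DG control 2 and with no low-count filter and a fit of only the groups compared (adjusted p 0.053 to 0.11, and 0.0018 to 0.11 over all alternatives). CDH2 lost the call with no low-count filter and total-count scaling (adjusted p 0.052 to 0.069, and 1.1e-04 to 0.069 over all alternatives). DNA replication and G1/S lost the call with both libraries that stand apart left out (adjusted p = 0.056, and 0.0023 to 0.46 over all alternatives). Metallothioneins lost the call without any 1 of high-glucose control 2 and 2-DG control 2 (adjusted p 0.051 to 0.15, and 0.0024 to 0.49 over all alternatives). Cytosolic ribosomal proteins lost the call without 2-DG control 2 and with both libraries that stand apart left out (adjusted p 0.15 to 0.56, and 9.9e-08 to 0.74 over all alternatives). MAP1LC3B and MKI67 passed without the 2 libraries that stand apart (adjusted p 0.0011 to 0.029).

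Deprivation and 2-DG share the high-glucose control, which by itself makes their fold changes correlate. 995 genes rose in both and 695 fell in both, where independent changes would give 450.1 and 314.5 (r = 0.391 and rho = 0.370 over 12879 genes). In 20 simulations of unchanged groups with a shared control the mean correlation was 0.501, above that in the data, and the mean covariance 0.00877, where the data gave 0.0791. Called in both were 0 genes up and 0 down, but groups without effects have few calls to share, so part of the overlap may still come from the shared control. With no shared library, deprivation without CGRP against 2-DG with CGRP, the latter with 434 changed genes (276 up, 158 down), gave 175 both up and 90 both down (85.6 and 46.8 if independent), r = 0.192 and rho = 0.212.

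2-DG against glucose-deprived control sets the inhibitor against the loss of glucose itself. ATF4 targets and ER chaperones were lower in 2-DG medium and genes of proliferation and sterol synthesis higher. DDIT3 went from 256 ± 8.91 to 13.7 ± 3.45 CPM (SD, n = 3, log2 fold change -4.23 ± 0.22, adjusted p = 1.3e-10). TXNIP went from 13.4 ± 0.257 to 705 ± 37.0 CPM (5.71 ± 0.07, adjusted p = 1.7e-17). HSPA5 went from 20596 ± 227 to 2267 ± 148 CPM (-3.18 ± 0.08, adjusted p = 1.7e-14). IL1B went from 78.5 ± 4.45 to 413 ± 24.6 CPM (2.40 ± 0.06, adjusted p = 1.7e-14).

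Here 10447 genes differed, 5256 higher and 5191 lower in 2-DG (1994 and 1393 at least 2-fold). The largest rises beside TXNIP were METTL7A (5.33 ± 0.40), CP (4.95 ± 0.60) and MAP2K6 (4.95 ± 0.35), and RAB7B, with 280 counts beside 2, a ratio of 135 with a 95% counting interval from 37.0 to 1120 (adjusted p = 3.2e-10). The largest falls were RAB39B (-7.23 ± 0.25), CMKLR2 (-5.98 ± 0.21), SCN9A (-5.02 ± 0.21), ERVE-1 (-5.01 ± 0.32) and LURAP1L (-4.51 ± 0.09) (adjusted p 4.2e-15 to 2.6e-06 for these 8 genes). Among the genes named in advance CALCRL (0.99 ± 0.21), RAMP1 (1.74 ± 0.19), ARRDC4 (3.13 ± 0.07) and MKI67 (1.87 ± 0.23) rose and JUN (-0.55 ± 0.05), ASNS (-1.83 ± 0.24), TRIB3 (-3.07 ± 0.08), SLC2A1 (-0.72 ± 0.08), HK2 (-1.11 ± 0.15), ULK1 (-0.64 ± 0.05), SQSTM1 (-1.41 ± 0.07) and MAP1LC3B (-2.26 ± 0.08) fell.

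Of 31 lists, 9 were higher and 6 lower in 2-DG than in deprived medium. Among ATF4 targets 26 of 28 fell, 2 rose and 0 did not pass (26 and 2 adjusted over the list alone, median -1.42, adjusted p = 7.7e-31). These included ATF3 (-3.14) and SESN2 (-2.88). Among ER chaperone and ERAD genes 20 of 21 fell, 0 rose and 1 did not pass (20 and 0 adjusted over the list alone, median -1.31, adjusted p = 6.5e-24). They included HERPUD1 (-2.26) and PDIA4 (-1.52). In cell cycle G2/M 20 of 20 rose, 0 fell and 0 did not pass (20 and 0 adjusted over the list alone, median 1.63, adjusted p = 1.1e-29). Among them were KIF20A (2.15) and CCNA2 (1.82). In cholesterol synthesis 21 of 23 rose, 0 fell and 2 did not pass (21 and 0 adjusted over the list alone, median 1.25, adjusted p = 1.7e-25). These included INSIG1 (2.69) and MSMO1 (1.68). In DNA replication and G1/S 20 of 21 rose, 1 fell and 0 did not pass (20 and 1 adjusted over the list alone, median 1.25, adjusted p = 4.3e-24). They included RRM2 (2.28) and MCM6 (2.05). Among interferon-stimulated genes 15 of 20 rose, 1 fell and 4 did not pass (16 and 1 adjusted over the list alone, median 1.24, adjusted p = 1.7e-17). Among them were IFIT3 (2.16) and OAS1 (2.02). Among NF-kB inflammatory genes 13 of 19 rose, 5 fell and 1 did not pass (13 and 5 adjusted over the list alone, median 1.65, adjusted p = 3.5e-11). These included TNF (2.18) and ICAM1 (1.63). Among heat shock genes 8 of 10 rose, 0 fell and 2 did not pass (8 and 0 adjusted over the list alone, median 0.83, adjusted p = 3.8e-05, adjusted p = 0.11 with an estimated correlation). The count was 12351 without the 2 libraries that stand apart and 10414 (59.6% higher) with total-count scaling.

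**Figure D4:**
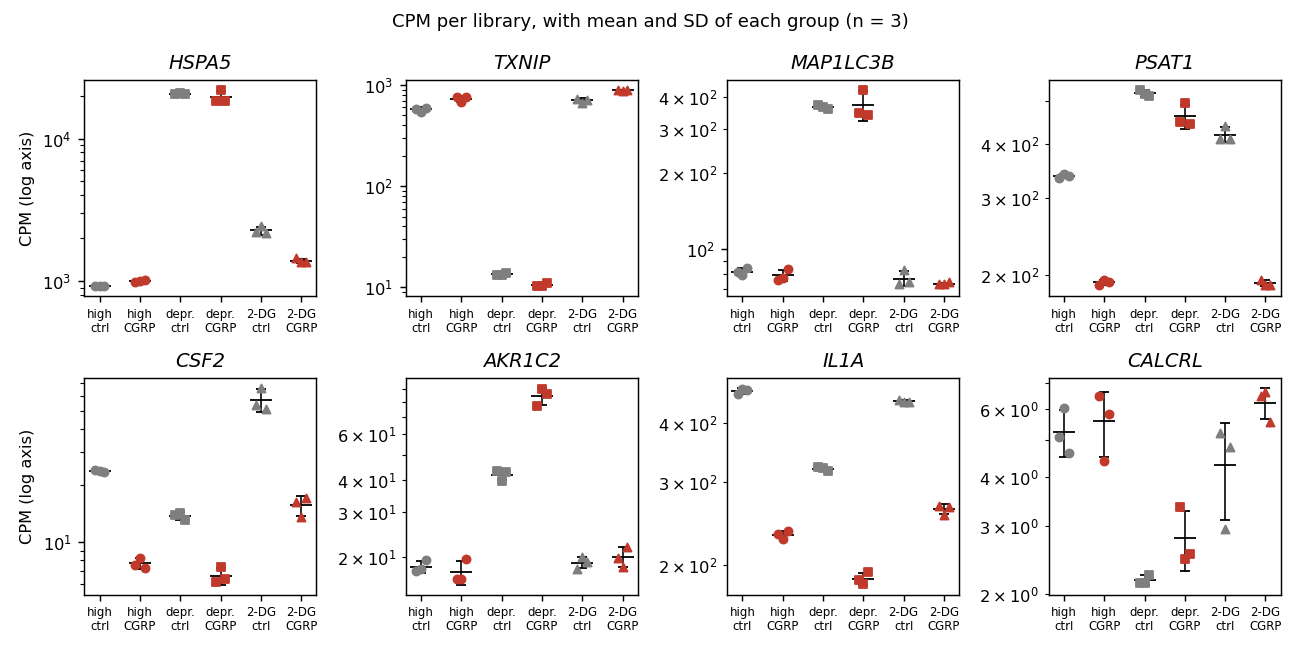
CPM of 8 genes (log axis) in each library, with the mean and SD of each group (n = 3), for control and CGRP in the 3 media (x axis). PSAT1 goes from 338 to 193 CPM with CGRP in high glucose and TXNIP from 574 to 13.4 CPM with deprivation.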

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

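In this part the tests of a length trend as part of the cause, of low depth and of a swap for the 2 libraries that stand apart, and the 3 tests on ATF4 targets, were chosen only after the result was seen. The results listed first stand here because the interaction test found the effect of CGRP to differ between media.

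Between deprived medium and high glucose the effect of CGRP differed in 282 genes. The log2 difference was positive for INHBE (2.37), FSD1 (1.51), FLRT1 (1.51), FGF1 (1.43), ARNT2 (1.32), TRIB3 (0.58) and SQSTM1 (0.53). It was negative for EDN2 (-2.71), STC1 (-1.96), TCAF2 (-1.65), ANGPTL4 (-1.38), SPRY1 (-1.25), TXNIP (-0.68) and ARRDC4 (-0.51). Of the lists, medians were 0.36 for NRF2 targets, 0.33 for ATF4 targets, -0.38 for hypoxia-responsive genes, -0.31 for interferon-stimulated genes, -0.17 for cell cycle G2/M and -0.16 for mitochondrially encoded genes. Of 50 groupings of the 12 libraries, the real one included, 4 gave as many genes (highest other 2686) and 7 as many lists (real 12, highest other 16), so chance cannot be excluded from these counts alone. Without deprived CGRP 2 the count of genes was 582.

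Between 2-DG medium and high glucose the effect of CGRP differed in 71 genes. The log2 difference was positive for HCG27 (0.85), TEC (0.78), TRAV8-1 (0.61), CCNG2 (0.56) and CYP1A1 (0.52), and negative for AGR2 (-1.82), HSPA5 (-0.82), CTHRC1 (-0.81), LAMB3 (-0.73) and NUCB2 (-0.71). Of the lists, medians were -0.48 for ER chaperone and ERAD genes, 0.14 for cholesterol synthesis, 0.23 for cell cycle G2/M and -0.25 for mitochondrially encoded genes. Of 50 groupings, the real one included, 7 gave as many genes (highest other 2735) and 34 as many lists (real 8, highest other 18), so chance cannot be excluded from these counts alone. In both interactions the grouping with the highest count exchanges the arms of 1 medium, which points to a structure of the samples: it turns the difference of the CGRP effects into their sum. Such groupings carry the CGRP effect itself, so these shares do not measure chance alone.

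For the 6 pairwise comparisons the 10 groupings are too few for a share under 0.05. The real grouping gave 787, 2354 and 2216 genes for CGRP in high-glucose, deprived and 2-DG medium. It gave 11011, 2513 and 10447 for deprivation, 2-DG and 2-DG against deprivation. The highest other gave 0 in each. For lists the real and highest other were 13 and 13, 11 and 9, 16 and 15, 16 and 16, 8 and 8, and 15 and 15 in the same order, with 2, 1, 1, 2, 2 and 2 groupings as high. The averaged effect of CGRP gave 3883 genes, and the other 49 groupings drawn at most 12. Those mix the arms, which widens their spread. Of 50 groupings 7 gave as many lists (real 14, highest other 17). Chance is excluded for neither count.

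Deprived CGRP 2 and 2-DG control 2 lay apart from their group mates. A trend with transcript length may be part of it: rho of the log2 ratio to the group mates against length had a size of at least 0.230 in both, and at most 0.155 in the other 16 libraries. Such a trend was not the whole cause, since the SD over genes after its removal was at least 0.316 in both and at most 0.140 in the others. Low depth and a swap were argued against by a lower total of 28.63M counts, above the 28.04M of another library, and by a distance to the group mates of at most 1.51 on the first component, where their groups lie 103.7 apart. What else set them apart, in the culture or in the handling of RNA, was not tested.

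ATF4 targets were lower with CGRP in high glucose and in 2-DG medium. A length trend between the arms is argued against, with adjusted p at most 6.74e-36 in both media after its removal. So is 2-DG control 2 in 2-DG medium, at 2.58e-57 without both libraries that stand apart. High glucose holds neither. Whether the arms carry exchanged labels cannot be told apart from a true fall: 9 genes that cAMP induces, outside the AP-1 and growth factor genes, had a median of -0.0709 in high glucose with 0 up and 1 down (NR4A1). A difference in culture state between the arms, such as medium age or density, also stays open as untested. That CGRP itself lowers ATF4 activity is a hypothesis.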

How the results depend on the processing

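Alternatives chosen after seeing the data are named above. Of 295 values of named genes all kept their direction and side of the threshold with RLE factors, 291 of 293 with DESeq2, 292 of 295 with the length offset, 287 with total-count scaling, 284 without both libraries that stand apart, 283 with no low-count filter, 287 of 289 with the stricter filter and 256 of 284 in fits of only the groups compared, and 0 reversed. Counts of genes stayed within 1.5 times for 9 of 9 comparisons with RLE factors, the stricter filter, total-count scaling and the length offset. Of 279 list medians compared over scalings, 31 changed sign, and 0 of these belonged to shifted lists.

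Numbers of replicates do not pair the samples: 0 of 18 correlations of same-numbered libraries were over 0.1 (-0.154 to 0.0536), and 5 of 18 libraries correlated best with their own number. With a replicate block the counts of genes were 781, 2380, 2277, 11113, 2573, 10554, 268, 68 and 3958, in the order of the comparisons, all within 1.5 times, and of named genes TEC did not pass in the interaction with 2-DG (adjusted p = 0.059).

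With no low-count filter 474 genes changed with CGRP in high glucose, 1463 in deprived medium, and 163 and 30 in the interactions. Without both libraries that stand apart counts were 3520, 5307 and 5249 for CGRP in high-glucose, deprived and 2-DG medium and 5997 for 2-DG. Interactions gave 2500 and 1092 and the average 7209. The high-glucose comparison holds neither, so its count rose through shared estimates such as spread. Fits of only the groups compared gave 3653, 141 and 1194 for CGRP, 1551 for 2-DG and 164 and 142 for the interactions. DESeq2 gave 507 and 227 for these. Other causes were not tested.

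With single libraries left out, counts of genes ran from 353 to 487 for CGRP in high glucose, 1282 to 2726 in deprived medium and 1447 to 1826 in 2-DG medium, 10064 to 10153 for deprivation, 1593 to 2078 for 2-DG, 9434 to 10088 for 2-DG against deprivation, 162 to 582 and 13 to 50 for the interactions and 3301 to 5334 averaged. The highest for the interaction with deprivation, 582, came without deprived CGRP 2. Counts of lists ran from 13 to 14, 11 to 14, 15 to 17, 16 to 16, 7 to 11, 14 to 18, 10 to 19, 6 to 11 and 13 to 16 in the same order, the highest for the interaction with deprivation (19) again without deprived CGRP 2. The cause was not tested.

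With an estimated correlation, which allows each list its own, lists shifted were 6 and 9 for CGRP in deprived and 2-DG medium, 10 for deprivation, 3 for 2-DG, 6 and 4 for the interactions and 9 averaged. Fry, which does not compare a list with other genes, called 17 for CGRP in deprived medium, 29 for deprivation, 14 for 2-DG, 26 for 2-DG against deprivation, 5 for the interaction with 2-DG and 23 averaged. Counts of overlap among genes changed at least 2-fold were 15 for high-glucose and deprived, 35 for high-glucose and 2-DG, and 25 for deprived and 2-DG medium, against 401, 574 and 733 with no fold threshold, since fewer genes pass.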

Other observations

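Mitochondrially encoded genes were lower with deprivation for several subunits: 8 of 13 fell, 1 rose and 4 did not pass (8 and 1 adjusted over the list alone, median -0.44, adjusted p = 0.13), with MT-CO3 (-1.14), MT-ATP6 (-1.01) and MT-CYB (-0.71) down and MT-ND1 (0.49) up. These genes were chosen after their values were seen.

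The tests of CGRP against the media were written after the gene lists and before each correlation was seen. One hypothesis was that CGRP in 2-DG medium counters what deprivation does. Over 12879 genes, with no shared library, log2 fold changes of deprivation and of CGRP in 2-DG medium had r = -0.451 (rho = -0.370), with 843 genes up with deprivation and down with CGRP (388.4 if independent) and 719 the other way (285.5). Without both libraries that stand apart r was -0.479 (rho = -0.407, 12878 genes), so these libraries did not make the relation. CGRP in high glucose and the step from deprived to 2-DG medium had r = 0.274 (rho = 0.199), while CGRP in deprived medium and 2-DG had r = -0.107 (rho = -0.0436), with 309 genes up with 2-DG and down with CGRP (95.5 if independent) and 194 the other way (67.8). The counts run opposite, while rho is near 0, which leaves this pair open. Not all values run against deprivation: in deprived medium CGRP lowered cell cycle G2/M (median -0.15), TXNIP (-0.34) and ARRDC4 (-0.30), and in each medium NF-kB inflammatory genes, as deprivation did. What lies behind the relation was not tested.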
